A study of Mus musculus with 12 samples.

How the data were processed

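The data are FPKM values of 24340 gene rows in 12 liver libraries of C57BL/6 mice. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected on magnetic beads, and libraries were made with a ThruPLEX kit. The deposited values are FPKM, fragments per kilobase of transcript scaled to the library's total, which the authors computed before deposit. Per the submitters' processing notes, HISAT2 2.1.0, Cufflinks (version not given), SAMtools 0.1.18-r580 and Cuffdiff 2.1.1 were used with the mm10 genome build. The roles and order of these tools, their settings and the gene annotation are not given in the sources used here. FPKM is relative to each library's own total, so a change in a few abundant genes shifts the values of all others, and FPKM summed to between 593025 and 769104 per library.

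Groups were taken from the sample titles: CTL or PPA, 0 h or 6 h, and a replicate number. The labels give neither the sex of the mice nor a sequencing batch. No read counts were used. Within a gene, low FPKM values lay on whole multiples of a step: over 5841 values of 2223 genes, 92.9% came within 0.1 of a whole number, where chance gives 20.0%. From these steps and transcript lengths of at least 3000 bases, depth was estimated at 3240000 to 5010000 fragments in the 0 h libraries and at 6940000 to 10010000 in the 6 h libraries. Depth and time therefore cannot be told apart, and low values are less precise at 0 h.

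Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, 10047 in all, on the log2(FPKM + 1) scale. A fold change on this scale understates the change of genes with low values. The 1285 rows of short non-coding RNA genes were left out, since poly(A) selection does not capture them reliably. Alb was listed at 0 in all 6 h libraries and at 17325.9 to 23772.6 FPKM at 0 h, and Apoe at 0 in the CTL_6h libraries and at 29426.7 to 52464.9 FPKM in all others. These zeros were taken as failed estimates, and both genes were left out. This was decided after seeing the data and departs from the design fixed earlier. The table holds 27 gene symbols that a spreadsheet had turned into date serials, 2 of which occur in 2 rows, and these genes are not named.

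Tests were made with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all tested genes, called at an adjusted p under 0.05. The contrasts were PPA against control at 0 h and at 6 h, 6 h against 0 h in control and in PPA mice, the mean PPA effect over both times, and the difference of the PPA effects (the interaction of PPA and time). Gene lists were tested with camera in limma, two-sided, at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Of 43 lists, 30 on function and 13 on cell type markers, 40 had at least 2 tested genes. With an estimated correlation no list was called in any comparison, so calls of lists rest on the preset value. Coordinates are from the GENCODE vM21 annotation of GRCm38, the assembly called mm10. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

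The genes named for each comparison followed a fixed rule. Its parts were the 10 called genes that rose most and the 10 that fell most, with non-overlapping groups where 2 groups were compared and a mean of at least 5 FPKM in the higher group, up to 4 members with the smallest p of each list that was called or had members past the threshold, 2 abundant members of each other list, and 10 genes of APAP metabolism and stress. Exceptions are named as such, and some genes covered by the rule are not reported here. Comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except where stated.

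The tests were tested on simulated data with the real genes' means, their moderated spread, equal in all groups, and known changes. Of genes changed by 1 on the log2 scale, 85.1% were recovered for PPA at 0 h, 83.6% for PPA at 6 h, 83.6% for APAP in control mice, 94% for APAP in PPA mice, 98.5% for the mean PPA effect and 52.2% for the interaction. All 10 lists shifted by 0.5 were recovered in each comparison and 0 of 30 unshifted lists were called by camera. Genes were simulated independently of each other, so this cannot tell how often camera calls unshifted lists whose genes vary together. For the PPA comparisons the simulations called 96 to 177 genes, against 1 to 14 in the real data. The adjustment is less strict where more genes change, so these shares may overstate the recovery in the PPA comparisons. Alternatives covered the pseudocount, the filter, 3 scalings, sample quality weights, robust moderation, the short RNA genes, summing rows that share a symbol, fitting only the groups compared, a replicate block, leaving out each library, and for lists an estimated correlation and fry. Removing each library's trend with transcript length, keeping the failed estimates, leaving out families with near-identical copies and adding the male-biased and female-biased members of a list as lists of their own were alternatives chosen after seeing the data.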

Results

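Liver RNA of C57BL/6 mice was measured by sequencing of poly(A)-selected RNA, in 12 libraries that form 4 groups of 3. The mice received 3-phenylpropionic acid (PPA), an aromatic acid that gut bacteria can form, in their drinking water for 4 weeks, or plain water. After a 16 h fast, acetaminophen (APAP), an analgesic that injures the liver in overdose, was given at 300 mg/kg, and livers were taken at 0 h or at 6 h. The labels do not make clear whether the mice of the 0 h groups were injected. The groups are named CTL_0h, PPA_0h, CTL_6h and PPA_6h, and each library carries its group and its replicate number. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the library's total), with between 9277 and 9535 genes at 1 FPKM or more in a library. The low values of sparsely read genes fell on steps of 1 fragment, from which each 0 h library held an estimated 3240000 to 5010000 fragments and each 6 h library 6940000 to 10010000. Levels below are mean FPKM ± SD over the 3 libraries of a group. Changes are log2 ratios of FPKM + 1 with their SE, and "rose" and "fell" refer to an adjusted p under 0.05 in limma.

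Time after APAP set the libraries apart most. The first principal component held 58.3% of the variance and placed the 0 h libraries between -32 and -29 and the 6 h libraries between 22.8 and 36.4. The second component, with 13% of the variance, spread the 6 h libraries from 28 in CTL_6h_4 and 21.2 in CTL_6h_2 to -18.5 in PPA_6h_1 and -24.7 in PPA_6h_2, with CTL_6h_3 at -8.3 and PPA_6h_5 at -0.1. Replicates within a group correlated at r = 0.976 or more across genes, and no pair of libraries was identical.

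**Figure D1:**
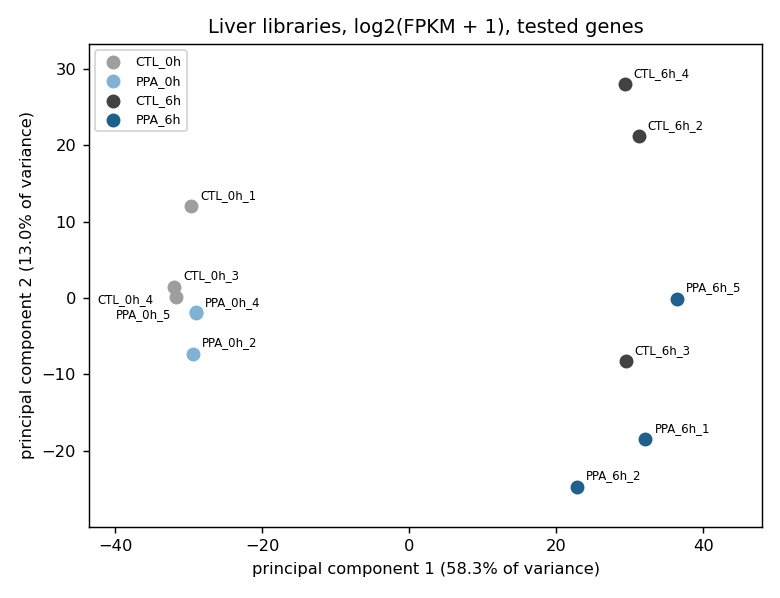
Principal components of log2(FPKM + 1) over the 10047 tested genes, with 1 point per library coloured by group. The first component (58.3% of variance) separates 0 h from 6 h, and along the second (13%) CTL_6h_3 at -8.3 lies nearer to the PPA_6h libraries than to CTL_6h_4 at 28.

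The first question was what APAP did to the liver of mice on plain water. Stress response genes rose steeply by 6 h, and genes of pericentral hepatocytes, the cells around the central vein that oxidise APAP, fell. Atf3, a stress-induced transcription factor, went from 0.567 ± 0.406 to 464 ± 43.0 FPKM (log2 change 8.24 ± 0.18, adjusted p = 2.11e-11), and the haem-degrading enzyme Hmox1 from 4.67 ± 1.33 to 712 ± 168 FPKM (6.97 ± 0.27, adjusted p = 3.56e-09). Among the strongest decreases were the glutamate transporter Slc1a2 (-4.52 ± 0.21) and glutamine synthetase, Glul, which went from 364 ± 11.9 to 33.6 ± 9.61 FPKM (-3.44 ± 0.20). Cyp2e1, the main enzyme that turns APAP into its reactive product, fell by 1.10 on the log2 scale (-1.10 ± 0.19, adjusted p = 0.0014), and Cyp1a2 also fell (-1.51 ± 0.21). In all, 1521 of 10047 tested genes rose and 1181 fell, 505 and 143 of them by 2-fold or more.

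Grouped by the lists fixed beforehand, all 21 of 21 immediate early and AP-1 genes rose, also when adjusted over the list alone, with a median change of 3.61 (adjusted p = 4.36e-24 by camera and adjusted p = 0.0797 with an estimated correlation). Beside Atf3 these were led by Maff (6.57 ± 0.17), Fos (6.46 ± 0.45), Egr1 (5.77 ± 0.29) and Jun (5.36 ± 0.23). Heat shock genes rose in 13 of 16, and in 13 adjusted over the list alone, with the co-chaperones Dnajb1 (5.27 ± 0.17) and Bag3 (3.58 ± 0.29) in front. The list had adjusted p = 3.26e-11 by camera and adjusted p = 0.147 with an estimated correlation. Of the integrated stress response genes 10 of 13 rose, and 10 adjusted over the list alone, among them Ddit3 (5.29 ± 0.31) and Chac1 (4.79 ± 0.49), a gene for a glutathione-degrading enzyme (adjusted p = 2.48e-07 by camera and adjusted p = 0.151 with an estimated correlation). The chaperones of the unfolded protein response moved less, with 4 of 17 higher past the threshold, also 4 adjusted over the list alone, and Hspa5 at 1.99 ± 0.18. As a list they had adjusted p = 0.0411 by camera and adjusted p = 0.706 with an estimated correlation. The list's call was lost without CTL_0h_1 or CTL_6h_3 (camera adjusted p up to 0.251). NRF2 targets and glutathione synthesis genes rose in 13 of 22, and in 13 adjusted over the list alone (adjusted p = 3.36e-08 by camera and adjusted p = 0.0891 with an estimated correlation). They include sulfiredoxin, Srxn1 (3.67 ± 0.17), the glutathione synthesis subunits Gclc (2.83 ± 0.24) and Gclm (0.54 ± 0.18), and Nqo1 (0.63 ± 0.21). Both metallothioneins rose, Mt1 by 3.54 ± 0.34 and Mt2 by 4.02 ± 0.46, 2 also adjusted over the list alone (adjusted p = 0.00352 by camera and adjusted p = 0.161 with an estimated correlation).

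Lists of inflammation were higher as well, other than that of interferon-stimulated genes (camera adjusted p = 0.83). Of the acute phase protein genes 14 of 24 rose and 1 fell, with the same counts adjusted over the list alone, and Serpina3m (1.57 ± 0.15), the fibrinogen chain gene Fgb (1.01 ± 0.14) and Apcs (1.26 ± 0.19) among the clearest. Tested as a list, they had adjusted p = 5.93e-06 by camera and adjusted p = 0.129 with an estimated correlation. Cytokine and chemokine genes rose in 7 of 15, and in 7 adjusted over the list alone, with Cxcl1 (4.79 ± 0.47) and Cxcl2 (2.64 ± 0.36) as neutrophil attractants (adjusted p = 0.0069 by camera and adjusted p = 0.496 with an estimated correlation). That list's call was lost without CTL_0h_4 (camera adjusted p up to 0.0697). NF-kappaB and STAT3 feedback genes rose in 8 of 14, and in 9 adjusted over the list alone, with Socs3 at 3.04 ± 0.23 and Nfkbiz at 4.40 ± 0.40. The list test returned adjusted p = 1.64e-05 by camera and adjusted p = 0.129 with an estimated correlation. All 3 measured neutrophil markers rose, also 3 adjusted over the list alone, S100a8 by 3.89 ± 0.48 and S100a9 by 2.92 ± 0.55 (adjusted p = 0.00407 by camera and adjusted p = 0.181 with an estimated correlation). Cytoskeleton and adhesion genes of injured cells rose in 19 of 29 and fell in 2, or 19 and 3 adjusted over the list alone. The list had adjusted p = 6.43e-09 by camera and adjusted p = 0.161 with an estimated correlation. They were led by the TWEAK receptor gene Tnfrsf12a (4.96 ± 0.28) and Cyr61 (4.58 ± 0.27). Of the p53 targets 5 of 11 rose, and 6 adjusted over the list alone, with Mdm2 at 2.23 ± 0.23 (adjusted p = 0.0069 by camera and adjusted p = 0.146 with an estimated correlation).

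Of the lists of hepatocyte genes, some fell. That of cholesterol synthesis rose in 11 of 26 (adjusted p = 0.000866 by camera and adjusted p = 0.582 with an estimated correlation). Gluconeogenesis (camera adjusted p = 0.065), periportal (0.101), fatty acid synthesis (0.919) and respiratory chain genes (0.585) were not called by camera, while fry called the first 2, higher (adjusted p = 0.0238 and 0.0343). Pericentral genes fell in 19 of 27, and in 19 adjusted over the list alone, with a median of -1.13 (adjusted p = 1.57e-11 by camera and adjusted p = 0.0797 with an estimated correlation). Among them were the ammonium transporter Rhbg (-2.81 ± 0.34) and Cyp2c37 (-1.53 ± 0.17). Bile acid synthesis and transport genes fell in 12 of 28 and rose in 1, or 14 and 2 adjusted over the list alone. As a list they had adjusted p = 0.000519 by camera and adjusted p = 0.129 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.72 ± 0.36), and the sterol 12-alpha-hydroxylase Cyp8b1 (-1.54 ± 0.14) were in this group. APAP metabolism genes fell in 5 of 19 and rose in 1, or 5 and 2 adjusted over the list alone (adjusted p = 0.0257 by camera and adjusted p = 0.496 with an estimated correlation). CAR and PXR targets fell in 7 of 18 and rose in 1, with the same counts adjusted over the list alone. Tested as a list, they had adjusted p = 0.0166 by camera and adjusted p = 0.497 with an estimated correlation. Glycine conjugation and medium-chain acyl-CoA genes, the route by which short aromatic acids are excreted, fell in 5 of 11, and in 5 adjusted over the list alone, with the glycine acyltransferase Glyat at -0.90 ± 0.19 (adjusted p = 0.00204 by camera and adjusted p = 0.246 with an estimated correlation). The call of the APAP metabolism list was lost without CTL_0h_4 or CTL_6h_4 (camera adjusted p up to 0.0619). Limits of this comparison are the greater depth of the 6 h libraries and skeletal muscle transcripts in CTL_6h_4, whose 15 muscle genes summed to 160.87 FPKM against 2.03 or less in every other library. No group was taken at 6 h without APAP. For every gene, in control and in PPA mice, hour of the day and time since the fast therefore cannot be told apart from APAP.

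The same time comparison in PPA mice asked what APAP did after 4 weeks of PPA. Atf3 rose from 0.391 ± 0.266 to 455 ± 53.3 FPKM (8.37 ± 0.18, adjusted p = 1.74e-11), Hmox1 from 8.46 ± 1.24 to 421 ± 171 FPKM (5.41 ± 0.27), and the heat shock protein genes Hspa1a (7.02 ± 0.62) and Hspa1b (6.01 ± 0.46), near-identical copies whose reads cannot be told apart with certainty, rose together. Slc1a2 (-5.31 ± 0.21), Glul (-4.23 ± 0.20) and Rhbg (-3.36 ± 0.34) fell, as did G0s2, an inhibitor of fat breakdown (-3.40 ± 0.31), and Cyp2e1 (-1.46 ± 0.19), Cyp1a2 (-1.52 ± 0.21) and Cyp3a11 (-1.24 ± 0.30, adjusted p = 0.00928). In all, 1505 of 10047 genes rose and 1330 fell, 430 and 219 of them by 2-fold or more.

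In PPA mice 18 of 21 immediate early and AP-1 genes rose, or 20 adjusted over the list alone, with a median of 2.49. The list test returned adjusted p = 1.06e-17 by camera and adjusted p = 0.0907 with an estimated correlation. Heat shock genes rose in 13 of 16, and in 13 adjusted over the list alone, Dnajb1 by 5.34 ± 0.17 and Hsp90aa1 by 3.50 ± 0.22 (adjusted p = 4.03e-13 by camera and adjusted p = 0.153 with an estimated correlation). NRF2 targets rose in 13 of 22, or 16 adjusted over the list alone, with Srxn1 at 3.91 ± 0.17 and Gclc at 3.56 ± 0.24. The list had adjusted p = 3.18e-09 by camera and adjusted p = 0.0657 with an estimated correlation. The metallothionein genes rose, Mt1 by 2.43 ± 0.34 and Mt2 by 3.13 ± 0.46, 2 adjusted over the list alone (adjusted p = 0.0118 by camera and adjusted p = 0.244 with an estimated correlation). Integrated stress response genes rose in 9 of 13, or 11 adjusted over the list alone, with Ddit3 at 5.41 ± 0.31 (adjusted p = 2.61e-06 by camera and adjusted p = 0.238 with an estimated correlation), and unfolded protein response chaperones in 6 of 17, and in 6 adjusted over the list alone. As a list they had adjusted p = 0.00435 by camera and adjusted p = 0.463 with an estimated correlation. Acute phase genes rose in 14 of 24, and 14 rose and 2 fell adjusted over the list alone, with Apcs at 2.83 ± 0.19 (adjusted p = 2.61e-06 by camera and adjusted p = 0.118 with an estimated correlation). Cytokines and chemokines rose in 5 of 15, or 6 adjusted over the list alone, with Cxcl1 at 4.12 ± 0.47. Tested as a list, they had adjusted p = 0.0167 by camera and adjusted p = 0.455 with an estimated correlation. NF-kappaB and STAT3 feedback genes rose in 7 of 14, and in 7 adjusted over the list alone (adjusted p = 0.00262 by camera and adjusted p = 0.241 with an estimated correlation), p53 targets in 4 of 11, and in 4 adjusted over the list alone (adjusted p = 0.027 by camera and adjusted p = 0.238 with an estimated correlation), and neutrophil markers in 3 of 3, also 3 adjusted over the list alone (adjusted p = 0.0118 by camera and adjusted p = 0.251 with an estimated correlation). Cytoskeleton and adhesion genes rose in 14 of 29 and fell in 2, or 15 and 3 adjusted over the list alone, with Tnfrsf12a at 4.50 ± 0.28 (adjusted p = 7.35e-06 by camera and adjusted p = 0.276 with an estimated correlation).

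Some lists of hepatocyte genes fell in PPA mice. That of cholesterol synthesis rose in 13 of 26 (adjusted p = 6.24e-05 by camera and adjusted p = 0.455 with an estimated correlation). Gluconeogenesis (camera adjusted p = 0.06, and adjusted p = 0.0262 by fry, lower), periportal (0.826), fatty acid synthesis (0.668) and respiratory chain genes (0.199) were not called by camera. Targets of PPAR-alpha, the receptor that drives fatty acid oxidation in the fasted liver, fell in 21 of 36, or 25 fell and 1 rose adjusted over the list alone, with a median of -0.93. The list test returned adjusted p = 1.05e-07 by camera and adjusted p = 0.42 with an estimated correlation. They include Cpt2 (-1.19 ± 0.15). The list mean was 5.34 in PPA_6h_1 and 5.40 in PPA_6h_2. In PPA_6h_5 it was 6.70, within the 6.52 to 6.94 of the PPA_0h libraries, so the fall rests on PPA_6h_1 and PPA_6h_2. In control mice 5 of these 36 fell, 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0649). The test of the difference between both responses had adjusted p = 1.31e-07 by camera and adjusted p = 0.719 with an estimated correlation. Pericentral genes fell in 19 of 27, and 19 fell and 1 rose adjusted over the list alone (adjusted p = 7.53e-11 by camera and adjusted p = 0.0657 with an estimated correlation). Amino acid catabolism genes fell in 15 of 31, or 17 adjusted over the list alone, among them Oat (-3.07 ± 0.28) and Bhmt (-0.94 ± 0.16). The list had adjusted p = 2.17e-06 by camera and adjusted p = 0.18 with an estimated correlation. Bile acid genes fell in 16 of 28 and rose in 2, with the same counts adjusted over the list alone, Cyp8b1 by -2.33 ± 0.14 (adjusted p = 6.73e-06 by camera and adjusted p = 0.0657 with an estimated correlation). CAR and PXR targets fell in 10 of 18 and rose in 3, or 11 and 3 adjusted over the list alone. As a list they had adjusted p = 0.000553 by camera and adjusted p = 0.251 with an estimated correlation. APAP metabolism genes fell in 7 of 19 and rose in 2, with the same counts adjusted over the list alone (adjusted p = 0.0299 by camera and adjusted p = 0.42 with an estimated correlation), a call lost without PPA_0h_2 or PPA_6h_5 (camera adjusted p up to 0.282). Glycine conjugation genes fell in 4 of 11, or 7 adjusted over the list alone, with Glyat at -0.62 ± 0.19 (adjusted p = 0.000573 by camera and adjusted p = 0.238 with an estimated correlation). Sex-dimorphic genes fell in 7 of 17 and rose in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.0344 by camera and adjusted p = 0.387 with an estimated correlation), a call lost without PPA_0h_2 or PPA_6h_2 (camera adjusted p up to 0.115).

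Set side by side, the APAP responses of control and PPA mice were alike in direction for most called genes. In both, 990 genes rose and 695 fell, where independent lists of these sizes would share 227.8 and 156.3. A single gene was called in opposite directions, the tight junction gene Cldn1, singled out after its values were seen. It fell from 10.8 ± 0.697 to 6.42 ± 2.27 FPKM in control mice (-0.71 ± 0.18, adjusted p = 0.0111) and rose from 10.2 ± 1.23 to 15.0 ± 1.46 FPKM in PPA mice (0.51 ± 0.18, adjusted p = 0.0493). The difference of the changes itself did not pass the test (1.22 ± 0.25, adjusted p = 0.269). Across the 10047 genes the changes correlated at Pearson r = 0.821 and Spearman rho = 0.738, with an orthogonal slope of 0.984. These are correlations across genes, which are not independent replicates, and the groups compared share no library.

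**Figure D2:**
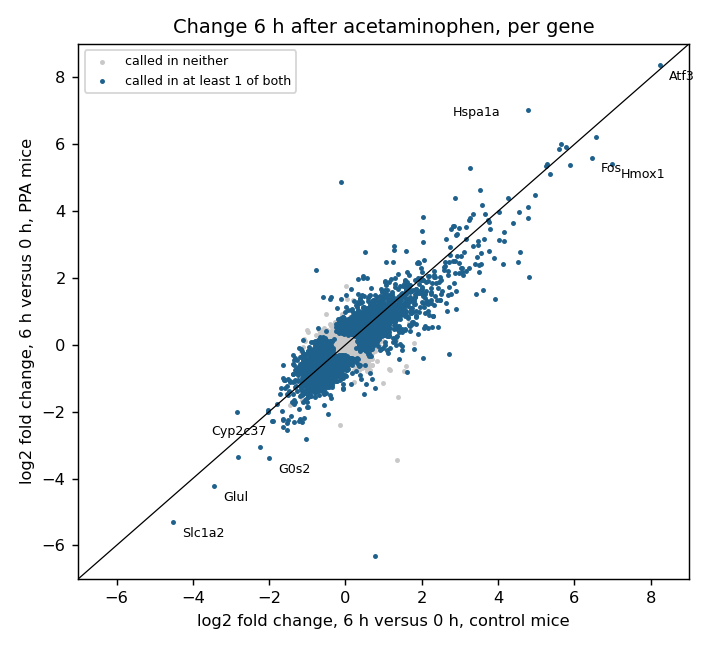
Log2 fold change from 0 h to 6 h after APAP in control mice (x axis) and PPA mice (y axis), 1 point per tested gene, on the log2(FPKM + 1) scale, with the line of equal change. Genes called in at least 1 of both comparisons are blue, and they run along the line, with Atf3 at 8.24 and 8.37 at the upper end and Slc1a2 at -4.52 and -5.31 at the lower end.

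At 0 h the question was whether PPA alone changed the liver. 3 of 10047 genes passed the test in limma. Moxd1, a gene of the dopamine beta-hydroxylase family (chromosome 10, 24223517 to 24302790 in mm10), rose from 0.173 ± 0.0808 to 14.5 ± 7.13 FPKM (3.61 ± 0.44, adjusted p = 0.01). The others were the near-identical MHC class I genes H2-Q8 (adjusted p = 0.000387) and H2-Q6 (adjusted p = 0.0429). H2-Q8 was listed close to 0 in all CTL_0h libraries and at 8.26 ± 1.42 FPKM with PPA, and H2-Q6 at 8.48 ± 2.38 FPKM without PPA and close to 0 with it, while the sum of both differed by -0.01 ± 0.26 (SE) on the log2 scale, so the change of either gene is uncertain. The enzymes that activate APAP did not pass the test. Cyp2e1 changed by -0.09 ± 0.19, adjusted p = 0.936, with a 95% interval from -0.51 to 0.32, Cyp1a2 by 0.32 ± 0.21 and Cyp3a11 by -0.17 ± 0.30. Gclc, which sets glutathione synthesis, changed by -0.29 ± 0.24, with an interval from -0.82 to 0.23.

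Small shifts of whole lists were called at 0 h although no member passed over all genes. In several lists the mean of PPA_0h_4 lay within the CTL_0h range, so their shifts rest on PPA_0h_2 and PPA_0h_5. It was 5.74 against 5.58 to 5.74 for unfolded protein response chaperones and 7.77 against 7.75 to 7.80 for acute phase genes. For gluconeogenesis genes it was 6.09 against 5.99 to 6.14, and for periportal genes 7.48 against 7.32 to 7.52. For Kupffer cell markers PPA_0h_2, at 2.95, lay within the CTL_0h range of 2.48 to 3.13. Kupffer cell and macrophage markers were higher in 14 of 15, with a median of 0.39 (0.17 without CTL_0h_4 and 0.24 without PPA_0h_5), none adjusted over the list alone. Tested as a list, they had adjusted p = 6.58e-05 by camera and adjusted p = 0.78 with an estimated correlation. Examples are Folr2 at 1.04 ± 0.29 and Cd163 at 0.53 ± 0.22. Gluconeogenesis and fasting genes were higher in 15 of 20, with 2 past the test adjusted over the list alone, led by Fkbp5 (0.79 ± 0.19) and Got1 (0.66 ± 0.18) (adjusted p = 0.000551 by camera and adjusted p = 0.78 with an estimated correlation). Sex-dimorphic hepatocyte genes were higher in 13 of 17, with 4 past the test adjusted over the list alone, among them C8b (0.62 ± 0.13) and the oxysterol hydroxylase gene Cyp7b1 (1.10 ± 0.26) (adjusted p = 0.00246 by camera and adjusted p = 0.78 with an estimated correlation), a call lost without PPA_0h_2 (camera adjusted p up to 0.0742). Unfolded protein response chaperones were higher in 13 of 17, with 1 past the test adjusted over the list alone, Herpud1 (0.60 ± 0.15). The list test returned adjusted p = 0.000577 by camera and adjusted p = 0.78 with an estimated correlation. Periportal genes were higher in 19 of 24, with 1 past the test adjusted over the list alone, Cdh1 (0.89 ± 0.22) (adjusted p = 0.00566 by camera and adjusted p = 0.78 with an estimated correlation), a call lost without CTL_0h_3 or PPA_0h_5 (camera adjusted p up to 0.107). Acute phase genes were higher in 20 of 24, none adjusted over the list alone (adjusted p = 0.0102 by camera and adjusted p = 0.78 with an estimated correlation), a call lost without CTL_0h_3, PPA_0h_2 or PPA_0h_5 (camera adjusted p up to 0.131).

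Lower at 0 h were mitochondrial respiratory chain genes, in 26 of 26 with a median of -0.15 (-0.08 without CTL_0h_1), none adjusted over the list alone (adjusted p = 0.000252 by camera and adjusted p = 0.78 with an estimated correlation). Part of this shift goes with a trend of the libraries with transcript length. CTL_0h_1, with the strongest trend (a correlation of -0.302), had the highest list mean, 8.10, and with the trend removed 22 of 26 were lower, with a median of -0.09 (camera adjusted p = 0.00183). PPAR-alpha targets were lower in 30 of 36, with a median of -0.20 (-0.31 without CTL_0h_3, -0.10 without PPA_0h_2 and -0.32 without PPA_0h_4) and none adjusted over the list alone (adjusted p = 0.00444 by camera and adjusted p = 0.981 with an estimated correlation), Pdk4 at -0.74 ± 0.25 and the acyl-CoA thioesterase gene Acot2 at -1.03 ± 0.43. That call was lost without CTL_0h_4 or PPA_0h_2 (camera adjusted p up to 0.0812). The mean of the PPAR-alpha list in PPA_0h_4, 6.94, lay within the 6.90 to 7.07 of the CTL_0h libraries. Cholesterol synthesis genes were lower in 23 of 26, none adjusted over the list alone (adjusted p = 0.03 by camera and adjusted p = 0.981 with an estimated correlation), a call lost without CTL_0h_3, PPA_0h_2 or PPA_0h_5 (camera adjusted p up to 0.87). The count of 3 genes was 1 without CTL_0h_1, PPA_0h_2 or PPA_0h_5 and 5 without CTL_6h_2, and otherwise between 2 and 4. At an unadjusted p under 0.05, 682 genes passed in limma, where chance gives 502. With simulated changes at this size of experiment, 85.1% of genes changed by 1 on the log2 scale and 20.9% of those changed by 0.5 were recovered. That simulation called 145 genes against 3 here, which makes the adjustment less strict, so recovery in the real comparison may be lower.

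At 6 h after APAP the question was whether the livers of PPA mice differed from those of control mice. 14 of 10047 genes passed, 6 higher and 8 lower with PPA. Moxd1 was again higher, at 11.7 ± 7.4 against 0.607 ± 0.825 FPKM (2.92 ± 0.44, adjusted p = 0.0379). Enho, the gene for the secreted metabolic peptide adropin (chromosome 4, 41638144 to 41640324 in mm10), rose from 12.7 ± 2.83 to 32.6 ± 2.67 FPKM (1.31 ± 0.22, adjusted p = 0.0438), and Cldn1 (1.14 ± 0.18), Sprr1a (2.02 ± 0.34), Serpina9 (1.22 ± 0.14) and the acute phase gene Apcs (1.15 ± 0.19) also rose. The fatty acid transporter Slc27a1 fell from 9.36 ± 0.586 to 4.04 ± 0.616 FPKM (-1.04 ± 0.12, adjusted p = 0.00669), and Pdk4, the kinase that spares glucose in fasting, from 10.8 ± 1.73 to 3.34 ± 0.929 FPKM (-1.46 ± 0.25, adjusted p = 0.0487).

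Also lower at 6 h were G0s2 (-1.86 ± 0.31), the activin antagonist follistatin, Fst (-1.92 ± 0.26), Cyp2c37 (-1.02 ± 0.17), Tymp (-0.85 ± 0.14) and Rnaset2a (-1.07 ± 0.13). The last has a near-identical copy, Rnaset2b, with which it may share reads. The remaining gene, listed as Zfp91Cntf, lay below 3 FPKM on average in every group and was named only after its values were seen (-1.69 ± 0.28). Slc27a1, Serpina9 and Rnaset2a passed with each of the 12 libraries left out in turn, Fst in 9 of the 12 and Moxd1 in 6, and the others in 2 to 5. Cyp2e1 was at -0.45 ± 0.19, adjusted p = 0.295, with a 95% interval from -0.87 to -0.04, and Hmox1 at -0.81 ± 0.27, adjusted p = 0.209.

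**Figure D3:**
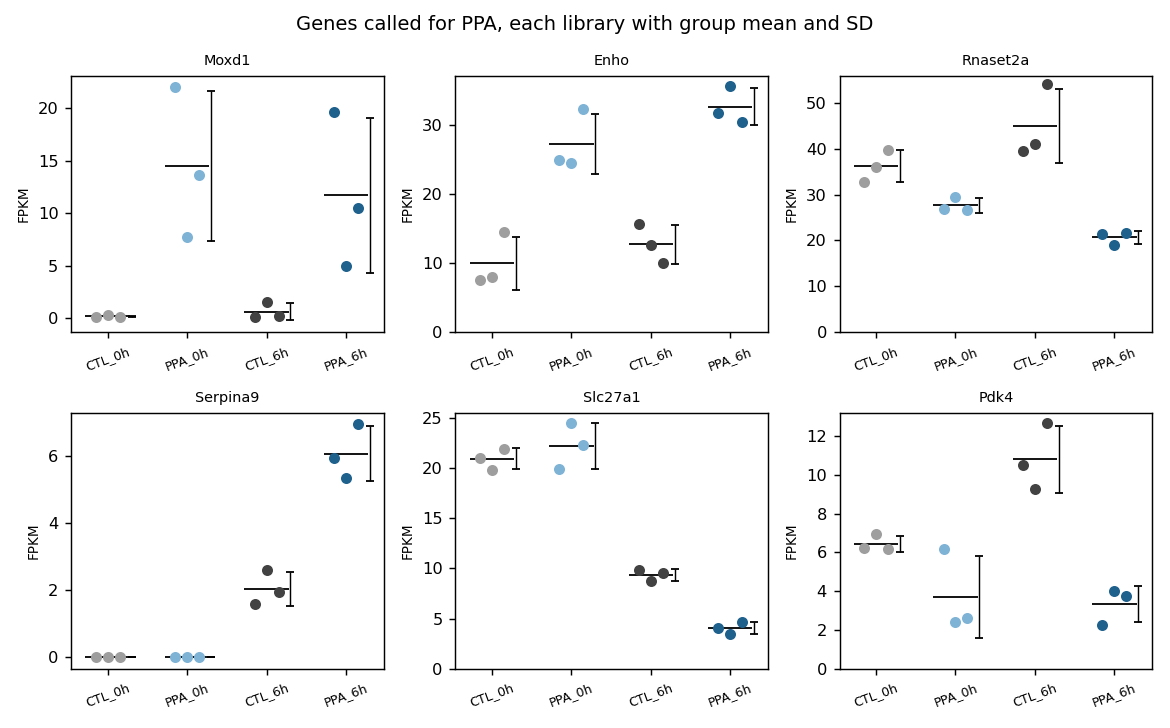
FPKM of 6 genes called for PPA, with 1 point per library, the group mean as a line and the SD (n = 3) as the bar beside it. Moxd1 and Enho are higher in all PPA libraries at both times, and Slc27a1 falls with time and is lower in PPA_6h, at 4.04 ± 0.616 against 9.36 ± 0.586 FPKM.

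As a group, PPAR-alpha targets were lower with PPA at 6 h in all 36 of 36 members, with a median of -0.81. The list had adjusted p = 5.41e-18 by camera and adjusted p = 0.514 with an estimated correlation. 1 of them fell over all genes and 27 adjusted over the list alone. The examples are Pdk4, above, Angptl4 at -1.05 ± 0.27 and Cpt1b at -1.05 ± 0.22. The PPA_6h samples differed among themselves. The mean log2(FPKM + 1) of the list was 5.34 in PPA_6h_1, 5.40 in PPA_6h_2 and 6.70 in PPA_6h_5, against 6.68 to 6.87 in the 3 CTL_6h libraries and 6.52 to 7.07 in the 0 h libraries. The median of the list without each library in turn lay between -1.16 and -0.62. Gluconeogenesis and fasting genes were lower in 17 of 20, with 11 lower and 1 higher past the test adjusted over the list alone, among them Pck1 (-0.61 ± 0.13) and G6pc (-0.92 ± 0.24) (adjusted p = 1.8e-05 by camera and adjusted p = 0.502 with an estimated correlation). Their list mean was 6.11, 5.73 and 6.17 in the PPA_6h libraries and 6.48 to 6.54 in the CTL_6h libraries. Amino acid catabolism genes were lower in 26 of 31 and respiratory chain genes in 26 of 26, none adjusted over the list alone (adjusted p = 7.98e-05 by camera and adjusted p = 0.514 with an estimated correlation for the first, adjusted p = 2.86e-05 by camera and adjusted p = 0.514 with an estimated correlation for the second). Both calls were lost with quantile normalization, where 8 lists were called. With the length trend removed the median of the respiratory chain list went from -0.23 (-0.15 without CTL_6h_4) to -0.17 (camera adjusted p = 4.58e-05). The mean of the respiratory chain list was 7.77 in CTL_6h_3, within the 7.65 to 7.79 of the PPA_6h libraries. CAR and PXR targets were lower in 15 of 18, 1 past the test over all genes and 2 adjusted over the list alone (adjusted p = 0.00049 by camera and adjusted p = 0.514 with an estimated correlation), a call lost without PPA_6h_5 (camera adjusted p up to 0.0983). Fatty acid synthesis genes were lower in 15 of 19 (adjusted p = 0.0174 by camera and adjusted p = 0.514 with an estimated correlation), a call lost without CTL_6h_3 or PPA_6h_2 (camera adjusted p up to 0.12), and autophagy and lysosome genes in 18 of 20 (adjusted p = 0.0453 by camera and adjusted p = 0.539 with an estimated correlation), a call lost without CTL_0h_4, PPA_0h_2, PPA_0h_4, PPA_0h_5, CTL_6h_3, CTL_6h_4 or PPA_6h_2 (camera adjusted p up to 0.235). Neither had members past the test adjusted over the list alone.

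Some of the stress and injury lists also differed with PPA at 6 h. Not called by camera were those of the integrated stress response (adjusted p = 0.448), p53 targets (0.474), cytokines and chemokines (0.474), NF-kappaB and STAT3 feedback (0.283), neutrophils (0.395) and NRF2 targets (0.821), with Gclc at 0.44 ± 0.24. Immediate early and AP-1 genes were lower in 20 of 21, with a median of -0.55 (-0.35 without PPA_6h_2), none past the test over all genes and 3 adjusted over the list alone. As a list they had adjusted p = 4.88e-05 by camera and adjusted p = 0.514 with an estimated correlation. Fosl2 was at -0.76 ± 0.16 and Btg2 at -1.37 ± 0.39. Cytoskeleton and adhesion genes of injured cells were lower in 25 of 29, with 3 adjusted over the list alone, Cyr61 at -1.13 ± 0.27 and the urokinase receptor gene Plaur at -1.36 ± 0.40 (adjusted p = 4.6e-05 by camera and adjusted p = 0.514 with an estimated correlation). Higher were heat shock genes in 14 of 16, with 1 adjusted over the list alone, Hspa1a at 2.32 ± 0.62 (adjusted p = 7.98e-05 by camera and adjusted p = 0.514 with an estimated correlation), unfolded protein response chaperones in 15 of 17, with 2 adjusted over the list alone, Sdf2l1 at 1.76 ± 0.50 and Manf at 0.91 ± 0.26 (adjusted p = 6.55e-05 by camera and adjusted p = 0.514 with an estimated correlation), and acute phase genes in 20 of 24, with 1 past the test over all genes and 2 adjusted over the list alone. Tested as a list, they had adjusted p = 5.11e-05 by camera and adjusted p = 0.502 with an estimated correlation. By library, in the order of CTL_6h_2, CTL_6h_3 and CTL_6h_4 against PPA_6h_1, PPA_6h_2 and PPA_6h_5, the list mean of immediate early genes was 6.51, 5.78 and 6.28 against 5.74, 5.14 and 5.94. It was 5.07, 4.48 and 5.26 against 4.46, 4.21 and 4.70 for cytoskeleton genes, 6.64, 7.33 and 6.52 against 7.35, 7.70 and 6.96 for heat shock genes and 5.87, 6.44 and 5.98 against 6.47, 6.72 and 6.28 for the chaperones. In these 4 lists CTL_6h_3 lay within the range of the PPA_6h libraries, and PPA_6h_5 within that of the CTL_6h libraries. Their shifts therefore rest on CTL_6h_2 and CTL_6h_4 against PPA_6h_1 and PPA_6h_2. The acute phase list was at 8.21, 8.73 and 8.65 against 8.92, 8.93 and 9.15. The count of 14 genes depended on single libraries. It was 813 without CTL_6h_3, 384 without PPA_6h_5, and 13 without CTL_0h_1. It was 3 without CTL_6h_2 or CTL_6h_4, 4 without PPA_0h_5, PPA_6h_1 or PPA_6h_2, 5 without CTL_0h_3 or CTL_0h_4 and 7 without PPA_0h_2 or PPA_0h_4. The test on the 6 h libraries alone called 0 genes in limma. With all libraries, at an unadjusted p under 0.05 there were 1492 genes in limma, where chance gives 502. The excess cannot be assigned to PPA, since another split of the 6 h libraries called 269 genes against 14 for the labels.

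**Figure D4:**
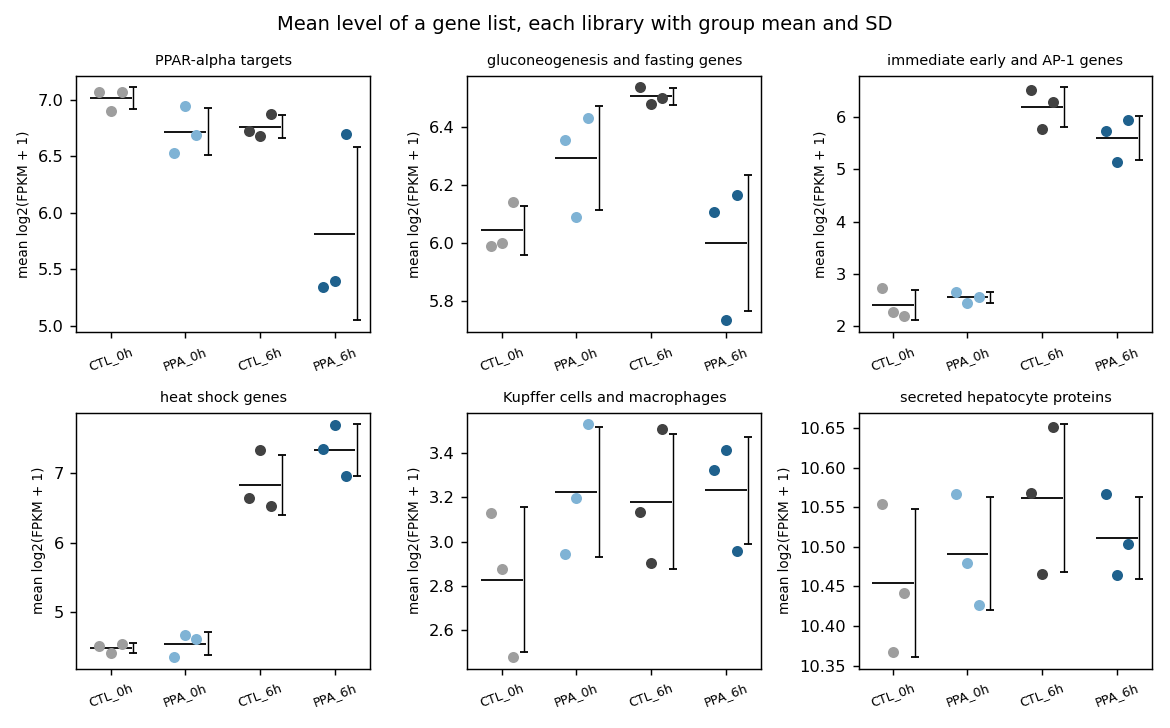
Mean log2(FPKM + 1) of 6 fixed gene lists, with 1 point per library, the group mean as a line and the SD (n = 3) as the bar beside it. PPAR-alpha targets stand at 5.34 and 5.40 in PPA_6h_1 and PPA_6h_2 and at 6.70 in PPA_6h_5, while the list of secreted hepatocyte proteins has a range of 0.10 within PPA_6h.

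Averaged over both times, 7 genes rose and 3 fell with PPA. The increases were Moxd1 (3.27 ± 0.31, adjusted p = 0.00129), the trefoil peptide gene Tff3 (2.41 ± 0.36), H2-Q8 (adjusted p = 0.00332), Enho (1.36 ± 0.15, adjusted p = 0.00332), the muricholic acid-forming enzyme Cyp2c70 (0.85 ± 0.13), the cystine transporter subunit Slc3a1 (0.78 ± 0.10) and Serpina9 (0.61 ± 0.10), which was listed at 0 in all 0 h libraries. The decreases were H2-Q6 (adjusted p = 0.0184), Pdk4 (-1.10 ± 0.18) and Rnaset2a (-0.72 ± 0.09). Enho went from 9.95 ± 3.86 to 27.2 ± 4.36 FPKM at 0 h and from 12.7 ± 2.83 to 32.6 ± 2.67 FPKM at 6 h. Moxd1, Enho, Slc3a1, Rnaset2a and H2-Q8 passed with each library left out in turn. The count was 335 without CTL_6h_3 and 178 without PPA_6h_5. It was 5 without CTL_6h_2, PPA_0h_5 or PPA_6h_2, 6 without CTL_0h_1, CTL_0h_3, CTL_0h_4, PPA_0h_2 or PPA_6h_1, 7 without PPA_0h_4 and 8 without CTL_6h_4. At the full 12 libraries, 1302 genes had an unadjusted p under 0.05.

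Of the 40 lists, 12 were called for the mean effect of PPA. PPAR-alpha targets were lower in 36 of 36, with 1 past the test over all genes and 20 adjusted over the list alone (adjusted p = 3.03e-16 by camera and adjusted p = 0.741 with an estimated correlation), and respiratory chain genes in 26 of 26, none adjusted over the list alone (adjusted p = 4.99e-08 by camera and adjusted p = 0.741 with an estimated correlation). Unfolded protein response chaperones were higher in 17 of 17, with 5 adjusted over the list alone, Sdf2l1 at 1.38 ± 0.35 and Manf at 0.70 ± 0.18 (adjusted p = 4.5e-07 by camera and adjusted p = 0.741 with an estimated correlation), acute phase genes in 22 of 24 and heat shock genes in 13 of 16, none adjusted over the list alone (adjusted p = 2.46e-06 by camera and adjusted p = 0.519 with an estimated correlation for the first, adjusted p = 0.00226 by camera and adjusted p = 0.761 with an estimated correlation for the second). Kupffer cell and macrophage markers were higher in 13 of 15, none adjusted over the list alone (adjusted p = 0.00226 by camera and adjusted p = 0.824 with an estimated correlation), a call lost without CTL_0h_4, PPA_0h_5 or CTL_6h_3 (camera adjusted p up to 0.122). The other called lists were CAR and PXR targets, lower in 15 of 18, fatty acid synthesis, in 14 of 19, glycine conjugation, in 10 of 11, immediate early genes, in 18 of 21, and cytoskeleton genes, in 22 of 29, and sex-dimorphic genes, of which 9 were higher and 8 lower. They had camera adjusted p between 0.00226 and 0.0401, and adjusted p = 0.741 to adjusted p = 0.878 with an estimated correlation. Adjusted over the list alone, 3 CAR and PXR targets and 3 glycine conjugation genes fell, 7 sex-dimorphic genes rose and 1 fell, and none passed in the other lists. The calls were lost without PPA_6h_5 (camera adjusted p up to 0.101) for CAR and PXR targets, without CTL_0h_3 (camera adjusted p up to 0.0905) for fatty acid synthesis and without CTL_6h_4 (camera adjusted p up to 0.0516) for cytoskeleton genes. For glycine conjugation the call was lost without CTL_0h_1, CTL_0h_3, PPA_0h_4, PPA_0h_5, CTL_6h_4 or PPA_6h_1 (camera adjusted p up to 0.134), for immediate early genes without CTL_0h_1, PPA_0h_4, PPA_0h_5, CTL_6h_2 or PPA_6h_2 (camera adjusted p up to 0.382), and for sex-dimorphic genes without CTL_0h_3, CTL_0h_4, PPA_0h_2, CTL_6h_2 or PPA_6h_5 (camera adjusted p up to 0.16).

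The last test asked whether the effect of PPA differed between 0 h and 6 h. H2-Q8 was the single gene past the threshold (adjusted p = 0.0398), with the read-sharing doubt given above, and 929 genes had an unadjusted p under 0.05. The count was 43 without CTL_6h_3, 16 without PPA_6h_5 and 0 in limma without CTL_0h_1, PPA_0h_2, PPA_0h_4, PPA_0h_5, CTL_6h_4 or PPA_6h_2. It was 1 without CTL_0h_3 or CTL_0h_4, a gene other than H2-Q8, which passed in 4 of the 12 fits with 1 library left out, those without CTL_6h_2, CTL_6h_3, PPA_6h_1 or PPA_6h_5. Gluconeogenesis and fasting genes, higher with PPA at 0 h and lower at 6 h, had the clearest list difference, with lower values in 19 of 20, 10 lower and 1 higher past the test adjusted over the list alone, and a median of -0.75. The list test returned adjusted p = 5e-10 by camera and adjusted p = 0.211 with an estimated correlation. Got1 stood at -1.30 ± 0.26, Tat at -1.10 ± 0.27 and Pck1 at -0.73 ± 0.18. It was also the one list that fry called (adjusted p = 0.0484). PPAR-alpha targets were lower in 35 of 36, none adjusted over the list alone, with a median of -0.65 (-0.35 without PPA_6h_1) (adjusted p = 1.31e-07 by camera and adjusted p = 0.719 with an estimated correlation). Immediate early genes were lower in 18 of 21, 2 adjusted over the list alone, with a median of -0.86 (-0.51 without CTL_6h_2 and -0.53 without PPA_6h_2) and Fosl2 at -0.98 ± 0.23. The list had adjusted p = 2.75e-05 by camera and adjusted p = 0.719 with an estimated correlation. Amino acid catabolism genes were lower in 28 of 31, 1 adjusted over the list alone (adjusted p = 2.75e-05 by camera and adjusted p = 0.719 with an estimated correlation). These tests rest on the same PPA_6h and CTL_6h libraries as the comparison at 6 h. The simulated recovery was 52.2% of genes changed by 1 on the log2 scale and 1.5% of those changed by 0.5. With 96 genes called in that simulation against 1 here, recovery in the real comparison may be lower.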

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

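The tests of explanations given here were chosen after the results were seen, while the interaction tests of genes and lists were planned. The PPA effect at 6 h minus that at 0 h passed the test for 1 gene, H2-Q8, with a log2 difference of -2.99 (adjusted p = 0.0398 in limma). H2-Q8 is listed close to 0 in CTL_0h, so this number depends on the pseudocount. Of 100 splits of the libraries drawn at random, 18 gave at least 1 gene, with up to 11, so chance cannot be excluded for this count.

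For 10 lists the median difference of the PPA effects was called by camera. Gluconeogenesis and fasting genes had a median of -0.75, immediate early and AP-1 genes of -0.86 (-0.51 without CTL_6h_2 and -0.53 without PPA_6h_2), PPAR-alpha targets of -0.65 (-0.35 without PPA_6h_1) and amino acid catabolism genes of -0.28 (-0.18 without PPA_6h_5), each called with every library left out in turn, with the p-values of both tests given for the interaction of PPA and time. Cytoskeleton and adhesion genes of injured cells had a median of -0.36 (-0.19 without CTL_6h_4, -0.22 without PPA_6h_2 and -0.54 without PPA_6h_5), with 24 of 29 lower and 1 past the test adjusted over the list alone (adjusted p = 0.00235 by camera and adjusted p = 0.719 with an estimated correlation), a call lost without CTL_6h_4 (camera adjusted p up to 0.0762). Periportal genes had -0.31, with 20 of 24 lower and 1 adjusted over the list alone (adjusted p = 0.00311 by camera and adjusted p = 0.719 with an estimated correlation), a call lost without PPA_6h_5 (camera adjusted p up to 0.0756). NF-kappaB and STAT3 feedback genes had -0.29, with 11 of 14 lower and 1 adjusted over the list alone (adjusted p = 0.0149 by camera and adjusted p = 0.719 with an estimated correlation), a call lost without CTL_0h_4 or PPA_6h_2 (camera adjusted p up to 0.0747). Heat shock genes had 0.54 (0.86 without CTL_6h_3, 0.33 without CTL_6h_4 and 0.23 without PPA_6h_2), with 13 of 16 higher and none adjusted over the list alone (adjusted p = 0.00787 by camera and adjusted p = 0.756 with an estimated correlation), a call lost without PPA_0h_2, CTL_6h_4 or PPA_6h_2 (camera adjusted p up to 0.091). CAR and PXR targets had -0.29 (-0.10 without CTL_6h_2 and -0.05 without PPA_6h_5), with 13 of 18 lower and 3 adjusted over the list alone (adjusted p = 0.0424 by camera and adjusted p = 0.719 with an estimated correlation), a call lost without CTL_0h_1, CTL_0h_3, PPA_0h_2, PPA_0h_5, CTL_6h_2, CTL_6h_3 or PPA_6h_5 (camera adjusted p up to 0.358). Kupffer cell and macrophage markers had -0.42 (-0.19 without CTL_0h_4, -0.22 without PPA_0h_5, -0.25 without CTL_6h_4 and -0.18 without PPA_6h_5), with 14 of 15 lower and none adjusted over the list alone (adjusted p = 0.0424 by camera and adjusted p = 0.891 with an estimated correlation), a call lost without CTL_0h_3, CTL_0h_4, PPA_0h_5, CTL_6h_4 or PPA_6h_5 (camera adjusted p up to 0.439).

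The wide spread of PPAR-alpha targets within PPA_6h, a range of 1.35 in the list mean, was weighed first. A swap of PPA_6h_5 with a control library at 6 h would not remove the spread, since the smallest range after such an exchange was 1.34. The CTL_6h libraries, at 6.68 to 6.87, lay near PPA_6h_5 at 6.70, so this cannot show whether labels were exchanged. The length trend of the libraries is argued against, since the range was 1.35 with the trend removed. So is a lower share of hepatocytes in some libraries, since the list of secreted hepatocyte proteins had a range of 0.10. What stays open is a difference between the samples in their response to PPA or APAP. It may be biological and was not tested, as the labels hold nothing to test it with.

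Other splits of the 6 h libraries gave a related pattern. The split that sets CTL_6h_2, CTL_6h_4 and PPA_6h_5 against the rest called 269 genes, against 14 for the labels, and with the same exchange the mean PPA effect had 38 against 10, which points to a structure of the samples other than the PPA label, and 10 splits cannot give a share under 0.05. Exchanged labels of CTL_6h_3 and PPA_6h_5 might account for it. The 20 genes with the smallest p for PPA at 0 h were signed by their change there. Families with near-identical copies, H2-Q6 and H2-Q8 among them, were left out of this choice. Over these genes PPA_6h_5 minus CTL_6h_3 was 0.20 ± 0.14 (SE over genes) in the labelled direction. With the genes chosen in a fit of the 0 h libraries alone it was 0.37 ± 0.16. Labels as given and labels exchanged therefore cannot be told apart by these genes. Enho and Moxd1, called for PPA partly from these same libraries, were in the labelled direction: Enho was 30.4 FPKM in PPA_6h_5 and 12.6 in CTL_6h_3, and Moxd1 was 10.5 FPKM in PPA_6h_5 and 1.56 in CTL_6h_3. H2-Q8, called higher for PPA, ran in the exchanged direction, at 9.31 FPKM in CTL_6h_3 and 4.22 in PPA_6h_5, as did H2-Q6, called lower, at 3.73 and 5.38, with the doubt about shared reads given below. A difference in how far the injury had gone in these samples also stays open and was not tested. CTL_6h_2, CTL_6h_4 and PPA_6h_5 also had the lowest estimated depth at 6 h, 6940000 to 8600000 fragments against 8900000 to 10010000. Their FPKM sums were the highest at 6 h, 701004 to 769104 against 593025 to 646269. Depth and library total therefore cannot be told apart from this split.

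The opposite values of H2-Q6 and H2-Q8 at 0 h were weighed last. Reads shared between near-identical genes and divided differently in each group could account for them, and the summed FPKM of both differed by -0.01 on the log2 scale between PPA_0h and CTL_0h, which is what that explanation needs. At 6 h the sum was lower with PPA, at 9.77, 8.58 and 9.6 FPKM in PPA_6h_1, PPA_6h_2 and PPA_6h_5. It was 13.94, 13.04 and 10.65 FPKM in CTL_6h_2, CTL_6h_3 and CTL_6h_4, and this difference was not tested. No biological explanation was tested.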

How the results depend on the processing

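The length trend, the kept failed estimates, the left-out near-identical families and the added sex-biased lists were chosen after the data were seen, and the other alternatives were planned. Counts of changed genes are given in the order PPA at 0 h (3), PPA at 6 h (14), mean PPA effect (10) and interaction (1), and only where they moved by over 1.5 times. With log2(FPKM + 0.1) they were 6 and 2 for PPA at 0 h and 6 h, and with log2(FPKM + 5) 1 and 22, with 0 for the interaction. Without a filter they were 1, 5 and 6 for the first 3. Rescaling all libraries to the same sum gave 7 at 6 h (2 higher, 5 lower), and quantile normalization 0 for the interaction. The sums used for rescaling included the failed estimates. Apoe, at 29426.7 to 33032.5 FPKM in PPA_6h and 0 in CTL_6h, thus entered the sums of only 1 of the groups compared at 6 h. Sample quality weights gave 10, 3631, 1417 and 519, and 4271 for APAP in control mice. Robust moderation gave 1 and 8 at 0 h and 6 h. With short RNA genes kept there were 4 at 6 h and 0 for the interaction, with the length trend removed 1, 8 and, for the interaction, 0, with failed estimates kept 2 for the interaction, and without near-identical families 1 at 0 h, 5 for the mean effect and 0 for the interaction. Fitting only the groups compared gave 8 at 0 h and 0 at 6 h. The counts of 0 are from limma, with 929 genes for the interaction and 1492 at 6 h at an unadjusted p under 0.05 with all libraries. The cause was not tested, apart from the families left out, where called genes were removed.

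Leaving out 1 library gave 1 to 5 genes for PPA at 0 h, 3 to 813 at 6 h, 5 to 335 for the mean effect and 0 to 43 for the interaction, the highest without CTL_6h_3 in the last 3, and 1830 to 2766 for APAP in control mice and 2003 to 3204 in PPA mice. Every gene called for PPA kept its sign in these fits. Lists called by camera numbered 5 to 13, 10 to 14, 9 to 13 and 8 to 10 in the same order. Calls by camera were also lost to other settings. With quantile normalization these were amino acid catabolism, respiratory chain, fatty acid synthesis and autophagy genes for PPA at 6 h, immediate early and glycine conjugation genes for the mean effect and CAR and PXR targets for the interaction. Raising the filter to FPKM of at least 5 lost autophagy genes at 6 h, immediate early genes, CAR and PXR targets and glycine conjugation for the mean effect, CAR and PXR targets and Kupffer cells for the interaction, chaperones and CAR and PXR targets for APAP in control mice, and APAP metabolism, sex-dimorphic genes and neutrophils in PPA mice. Sample quality weights lost fatty acid synthesis and autophagy at 6 h, periportal genes and Kupffer cells for the interaction, APAP metabolism, chaperones and CAR and PXR targets for APAP in control mice, and APAP metabolism and sex-dimorphic genes in PPA mice. The replicate block lost cholesterol synthesis at 0 h, fatty acid synthesis at 6 h, fatty acid synthesis, sex-dimorphic genes and Kupffer cells for the mean effect, and chaperones for APAP in control mice. Without a filter sex-dimorphic genes were lost at 0 h and for the mean effect, CAR and PXR targets for the interaction and neutrophils for APAP in PPA mice. The other losses were cholesterol synthesis at 0 h and CAR and PXR targets and Kupffer cells for the interaction with log2(FPKM + 5), immediate early genes for the mean effect with log2(FPKM + 0.1), autophagy at 6 h and sex-dimorphic genes for the mean effect with median-ratio scaling or a common sum, and sex-dimorphic genes for APAP in PPA mice and CAR and PXR targets for the interaction with the length trend removed. With an estimated correlation 0 lists were called in each of the 6 comparisons, and fry called 0 for PPA at 0 h, at 6 h and for the mean effect, and 1 for the interaction. The correlation of the APAP responses was 0.786 with log2(FPKM + 0.1), 0.849 with log2(FPKM + 5), 0.797 without a filter, 0.855 with FPKM of at least 5, and 0.764 to 0.847 with 1 library left out. With quantile normalization 1304 genes rose and 1598 fell with APAP in control mice, against 1521 and 1181, and 1398 rose and 1627 fell in PPA mice, against 1505 and 1330, so the majority turned in both. With PPA at 0 h 2 rose and 0 fell in limma under that setting. For the mean PPA effect, with 7 higher and 3 lower, the majority turned with sample quality weights (596 and 821), the replicate block (2 and 4), without CTL_6h_3 (146 and 189) and without PPA_6h_5 (53 and 125).

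No pairing by replicate number was seen. Libraries of the same number deviated from their group means with r from -0.282 to 0.086, and libraries of different numbers with r from -0.282 to 0.374. These correlations cannot exclude that samples of the same number are linked. With the replicate number as a block, 1 gene was called for PPA at 6 h, 6 for the mean effect and 0 for the interaction in limma. The gene at 6 h was not among the 14 called without the block. Of the 6 for the mean effect, 3 were among the 10 called without it. The block reversed 2 changes that had not passed the test, at 0 h with PPA, to 0.002 for Cyp3a11 and 0.026 for Gclc, and the cause was not tested.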

Other observations

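The tests of explanations and the split of the sex-dimorphic list given here were chosen after the results were seen, and the other list tests were planned. Cholesterol synthesis genes, the targets of SREBP2, were called higher as a list by camera 6 h after APAP in both control and PPA mice. In control mice 11 of 26 rose and 1 fell, or 13 and 1 adjusted over the list alone, with the sterol demethylase Cyp51 at 1.62 ± 0.33. As a list they had adjusted p = 0.000866 by camera and adjusted p = 0.582 with an estimated correlation. In PPA mice 13 rose and 1 fell, or 15 and 1 adjusted over the list alone, with Sqle at 3.09 ± 0.53 and Cyp51 at 1.89 ± 0.33 (adjusted p = 6.24e-05 by camera and adjusted p = 0.455 with an estimated correlation). The interaction of PPA and time was not called for this list (camera adjusted p = 0.409). Genes of the circadian clock and its output, whose levels depend on the hour of the day, rose in 11 of 20 and fell in 2 in control mice, or 11 and 3 adjusted over the list alone (adjusted p = 0.000311 by camera and adjusted p = 0.129 with an estimated correlation), and rose in 7 and fell in 1 in PPA mice, or 11 and 2 adjusted over the list alone. Tested as a list, they had adjusted p = 0.00435 by camera and adjusted p = 0.238 with an estimated correlation. Nr1d2 was at 1.31 ± 0.15 and Nfil3 at 1.26 ± 0.15 in control mice and at 1.18 ± 0.15 and 1.19 ± 0.15 in PPA mice. The labels give no hour of collection, so time after APAP and hour of the day cannot be separated.

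Among markers of other cell types only neutrophils were called by camera for the time after APAP, in both control and PPA mice. The alternative test, fry, also called platelets in control mice, higher (adjusted p = 0.0459), and in PPA mice adipocytes, lower in 2 of 2 genes (adjusted p = 0.0145), cholangiocytes, higher (adjusted p = 0.0337), and cell cycle genes, higher (adjusted p = 0.0167). Lists of endothelial cells, stellate cells, cholangiocytes, monocytes, platelets, erythroid cells, adipocytes and pancreas and gut epithelium, and those of interferon-stimulated genes, aryl hydrocarbon receptor targets, cell cycle genes and secreted hepatocyte proteins, were called by camera in none of the 6 comparisons. Among the members of the sex-dimorphic list at 0 h, the male-biased genes were higher with PPA in 11 of 13, with a median of 0.29 and none past the test over all genes (adjusted p = 3.46e-05 by camera and adjusted p = 0.714 with an estimated correlation). Selenbp2 was at 1.90 ± 0.41 and Serpina1e at 0.58 ± 0.19. The 4 female-biased genes had a median of -0.21 (camera adjusted p = 0.516). For PPA at 6 h 7 male-biased genes were higher and 6 lower (adjusted p = 0.322 by camera and adjusted p = 0.831 with an estimated correlation).

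Skeletal muscle transcripts stood out in CTL_6h_4. Muscle tissue in that sample is a candidate source, since 9 of 10 other muscle genes, beyond the 5 seen first, were at least 5 times the next library there. Acta1 was at 23.2 FPKM and Ckm at 20.1, against 0.168 and 0.177 or less in every other library. A length trend of the library is argued against, since the muscle genes summed to 2.03 FPKM in CTL_0h_1, the library with the strongest such trend. 1 of the 15 muscle genes, Mylpf, passed the filter, and no muscle gene was called for PPA.

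Other splits of the samples were counted for each comparison. For PPA at 0 h, APAP in control mice and APAP in PPA mice, 1 of 10 splits each, the real one, gave as many genes, 3, 2702 and 2835, with 0 in the highest of the other splits in limma. For PPA at 6 h 2 of 10 splits did, the real one with 14 and another with 269. 10 splits cannot give a share under 0.05. For the mean PPA effect 3 of 100 splits gave 10 genes or more, with up to 38, and without near-identical families, a count added after the results were seen, 4 of 100 gave 5 genes or more, with up to 34. Both shares are under 0.05, with no adjustment over the comparisons counted. A split other than the labels called the most genes in each count, so these shares do not exclude chance. The split with most genes in both keeps the 0 h labels and exchanges CTL_6h_3 with PPA_6h_5, which points to a structure of the 6 h samples other than the PPA label. At 6 h that split also goes with estimated depth and FPKM sum, as given above.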
